A study of Danio rerio with 12 samples.

How the data were processed

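Total RNA was taken from the eyes of juvenile zebrafish with TRIzol and made into mRNA libraries, per the labels' protocols, with 3 libraries in each of 4 groups. The authors deposited one table for the whole series, with a signal value per gene and library whose unit its header does not name. The deposited values have decimals and cannot be told apart as FPKM or TPM, and no read counts were used here. The submitters' processing notes name FastQC, Trimmomatic, Trim Galore, HISAT2, STAR, featureCounts, StringTie, DESeq2 and edgeR, and the builds GRCz11 and danRer11, without saying which made these values. All 12 value columns were joined to their library by the sample names, and none was left unmapped.

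The table holds 7955 genes: 5600 with an Ensembl gene ID, of which 5422 have a symbol, and 2355 named as new genes, which entered the counts but no gene list. For 93.2% of the genes the largest ratio between 2 group means was at least 2, and for 99.95% at least 1.5, so the genes had been chosen for differing between groups. Of 5 common reference genes looked for, 1 was listed. The number of genes at 0 was 371 to 447 in control libraries, 494 to 703 at the low dose, 99 to 131 at the high dose and 211 to 242 with the probiotic. The single most abundant gene held 7.3 to 14.1% of a library's sum. Without counts, the depth behind a value is unknown and no counting interval is given.

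The values were used as scaled by the authors, as log2(value + 1), with no filter on low values. Linear models with limma 3.58.1 in R 4.3.3 were fitted to all 12 libraries at once, with a mean per group and a variance trend, and 5 contrasts were tested with Benjamini-Hochberg adjustment over the 7955 genes of each contrast at an FDR of 0.05. The plan had named an edgeR count test first and limma for a table without counts, and the second was used. On data simulated for high dose against control over 7955 genes, the fit recovered 8% of genes changed by 0.25 on the log2 scale, 34% at 0.5, 92% at 1 and 98% at 2, with 4 calls among 7755 unchanged genes. The 50 genes changed at each size were drawn from genes with a control mean log2(value + 1) of at least 1. Recovery among genes with lower values was not measured.

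Of 31 gene lists fixed before the data were examined, 27 had at least 5 listed members and were tested with limma's fry, adjusted over the lists. Fry tests each list by itself, on genes chosen for differing between groups. A test against background genes was not made, since the table holds no set of unchanged genes. Symbols were matched to the lists ignoring case, and a symbol in capitals also matched list members that differ from it only by a copy suffix. Of these, 1 symbol that matched both photoreceptor lists was left out of both. The other choices fixed before the data were examined were the comparisons, the tests and the rule for named genes. That rule takes the 6 largest rises and falls in the 3 main comparisons and 3 in each of the other 2, among genes past the FDR whose groups do not overlap, with a mean of at least 1 in the higher group and a symbol that is no clone name. In the main comparisons it adds the 2 members of each list with the smallest adjusted p, to at most 30 genes per comparison. The genes listed here for jumps inside a group, the yolk and antigen presentation genes given per library, and values of a named gene in other groups were chosen after their values were seen.

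Agreement of the doses and the overlap with the probiotic comparison were set beside 50 simulations each, with unchanged groups that share the control libraries, or with a probiotic group that has the high dose means. Mean log2 levels of tissue lists were compared with exact two-sided permutation tests of 3 against 3, whose smallest p is 0.1. The alternatives were median-ratio and upper-quartile scaling over listed genes, pseudocounts of 0.1 and 0.5, a minimum mean of 1, a replicate block, fits of 2 groups alone, an FDR of 0.01, a log2 fold change of at least 1, and leaving out each replicate. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.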

Results

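RNA sequencing measured gene expression in the eyes of juvenile zebrafish after 30 days of exposure to BDPrB, a difluorinated butoxybenzene with a propylcyclohexyl side group. It is a liquid crystal monomer of the kind used in display screens. The 12 libraries fall into 4 groups of 3: a vehicle control, a low dose of 10 µg/L, a high dose of 100 µg/L, and the high dose with feed that carried the probiotic bacterium Lactobacillus brevis Lb-0401. The labels and the series text leave open whether this feed was given during the exposure or after the fish had been withdrawn from the monomer. The table used here lists 7955 genes with one expression value per library. It is a chosen part of the transcriptome, because 99.95% of the listed genes had a ratio of at least 1.5 between the means of some pair of groups. Counts of changed genes are therefore counts among listed genes and do not describe the whole transcriptome. The sequencing depth is unknown, and the values summed to between 220470 and 318895 per library. The median coefficient of variation within a group was 13.8 to 17.6% among genes with a group mean of 1 to 10, and 25.6 to 37.4% at 0.1 to 1. It was 2.4 to 4.6% among the 38 to 53 genes per group with a mean of at least 1000. The labels call the libraries biological replicates without naming the fish or pools behind each, so the p-values measure only the spread between these libraries. Some genes jumped between values near 0 and high values inside a group, such as NDUFS4, SPOCK3, epcam and RCVRN below, so a gene listed at or near 0 is not shown to be unexpressed. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Values are given as mean ± SD with n = 3 per group, ratios are ratios of group means, and adjusted p-values of genes come from limma.

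The comparison of the high dose with the control asks what the monomer did to expression in the eye. Genes of the surface epithelium, haemoglobins and interferon-stimulated genes were higher at the high dose, and lens crystallins, photoreceptor genes and inflammatory cytokine genes were lower. Of the 29 listed epidermal keratin and cornea genes, 25 rose and 3 fell, with a median log2 fold change of 2.27. The epithelial keratin gene krt93 (ENSDARG00000044976) was listed at 0 in all 3 control libraries and at 98.1, 101 and 93.5 in the high dose libraries. The annexin gene anxa1c (ENSDARG00000104359) stood at 219 ± 4.76 against 32.9 ± 1.24, a 6.66-fold ratio (limma adjusted p = 1.08e-12). Outside the list, the transglutaminase genes tgm1l2 (ENSDARG00000101595) and tgm1l3 (ENSDARG00000005913), relatives of the enzyme that cross-links the outer layers of skin, rose from 1.01 ± 0.153 to 131 ± 1.99 and from 0.727 ± 0.0629 to 110.1 ± 3.04. All 12 listed erythrocyte genes rose, with a median of 1.25, and the alpha-globin gene hbaa1 (ENSDARG00000097011) went from 134 ± 6.49 to 1210 ± 45.3.

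Of the 36 listed interferon-response genes, 31 rose and 1 fell at the high dose (median log2 fold change 1.2). The ubiquitin-like antiviral gene isg15 (ENSDARG00000086374) rose from 16.6 ± 1.52 to 58.9 ± 2.13, and the antiviral GTPase gene mxb (ENSDARG00000004953) from 0.86 ± 0.103 to 7.1 ± 0.726. Leukocyte and antigen presentation genes rose in the same comparison, 24 of 36 with 5 lower and a median of 0.7. Of the 39 listed extracellular matrix genes, 25 rose and 9 fell (median 0.71). Within that list the collagen gene COL1A1 (ENSDARG00000035809) rose from 26.2 ± 1.31 to 97.8 ± 2.52, and the metalloproteinase inhibitor gene TIMP2 (ENSDARG00000075261) fell from 182 ± 8.89 to 6.28 ± 0.719. Xenobiotic metabolism genes rose in 26 of 36 cases with 3 lower (median 0.68). All 5 listed digestive gland genes rose, at low values: serpina1 (ENSDARG00000090286) stood at 0.942 ± 0.19 against 0.0278 ± 0.0482. The yolk precursor gene vtg1 (ENSDARG00000092233), which the liver of egg-laying females expresses, stood at 35.8 ± 1.4 against 0.0315 ± 0.0451. Its relative vtg6 (ENSDARG00000016825) was listed at 0 in all 3 control libraries and at 5.03, 4.13 and 4.9 in the high dose libraries. In the fatty acid list, 17 of 29 genes rose and 9 fell, and the mitochondrial uncoupling protein gene UCP2 (ENSDARG00000043154) went from 56.2 ± 2.38 to 131 ± 3.77, while the lipase gene LIPG (ENSDARG00000031044) went from 9.15 ± 0.683 to 19.9 ± 0.198.

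None of the 47 listed lens genes rose at the high dose and 42 fell (median log2 fold change -0.75). The crystallin gene CRYBB2 (ENSDARG00000053512) fell from 12768 ± 77.5 to 6866 ± 58.7, and crygm2b (ENSDARG00000115234) from 3556 ± 48.7 to 1530.2 ± 22.3. Lens genes made up 39.8 to 40.6% of the listed sum in control libraries and 24.1 to 24.3% in high dose libraries. Of the 15 rod phototransduction genes 10 fell and 1 rose (median -0.58), and of the 18 cone genes 11 fell and 3 rose (median -0.55). The retinoid-binding protein gene rbp3 (ENSDARG00000059163) fell from 853 ± 15.3 to 505 ± 5.22, and the retinol dehydrogenase gene RDH10 (ENSDARG00000012369) from 32.1 ± 1 to 11.4 ± 1.87. Their list, the visual cycle, had 6 genes higher and 5 lower, with a median of 0.11 although the list test pointed down. Of the 31 inflammatory cytokine and complement genes, 19 fell and 3 rose (median -0.81). The cytokine gene il1b (ENSDARG00000098700) went from 399 ± 4.42 in control to 1.41 ± 0.618, and the neutrophil chemokine gene cxcl8a (ENSDARG00000104795) from 235 ± 1.49 to 2.84 ± 0.352. Outside that list, the granulocyte growth factor gene csf3b (ENSDARG00000098752) went from 181 ± 3.14 to 0.467 ± 0.0651. Also outside it, the leptin gene lepb (ENSDARG00000045548) fell from 252 ± 6.11 to 0.583 ± 0.17, scpp8 (ENSDARG00000093124) from 429 ± 16.4 to 0.258 ± 0.107, and the collagenase gene mmp13a (ENSDARG00000012395) from 71.9 ± 16.2 to 0.0564 ± 0.0978. The parvalbumin gene pvalb5 (ENSDARG00000032836) was listed at 0 in every control library and at 482, 520 and 511 at the high dose, and malb (ENSDARG00000030094) at 0 and at 71.3, 78.4 and 81.7.

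In limma's test 5830 of the 7955 listed genes passed an FDR of 0.05, 3869 higher and 1961 lower, and 2385 of them changed at least 2-fold. Every one of the 27 gene lists with at least 5 listed members passed limma's fry, a rotation test of whether a list's genes move on balance one way (adjusted p = 1.04e-11 for the keratins, 7.61e-11 for the inflammatory genes, 9.27e-11 for the interferon genes and 7.75e-10 for the lens genes). With the values rescaled by the median ratio over listed genes, 52.7% of the called genes were higher in place of 66.4%, and the median of all listed genes moved from 0.31 to 0.08. After that scaling the medians of the visual cycle (-0.33) and apoptosis lists (-0.23) had reversed. In limma's fry 4 lists no longer passed under a rescaling. The antioxidant median went from 0.59 to 0.3 under median-ratio and 0.36 under upper-quartile scaling (adjusted p = 0.942 and 0.0796 by limma's fry), and the cholesterol median from 0.32 to 0.09 and 0.12 (adjusted p = 0.637 and 0.0593 by limma's fry). The immediate early median went from 0.7 to 0.26 under median-ratio scaling (adjusted p = 0.128 by limma's fry), and the fatty acid median from 0.47 to 0.23 under upper-quartile scaling (adjusted p = 0.813 by limma's fry).

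**Figure D1:**
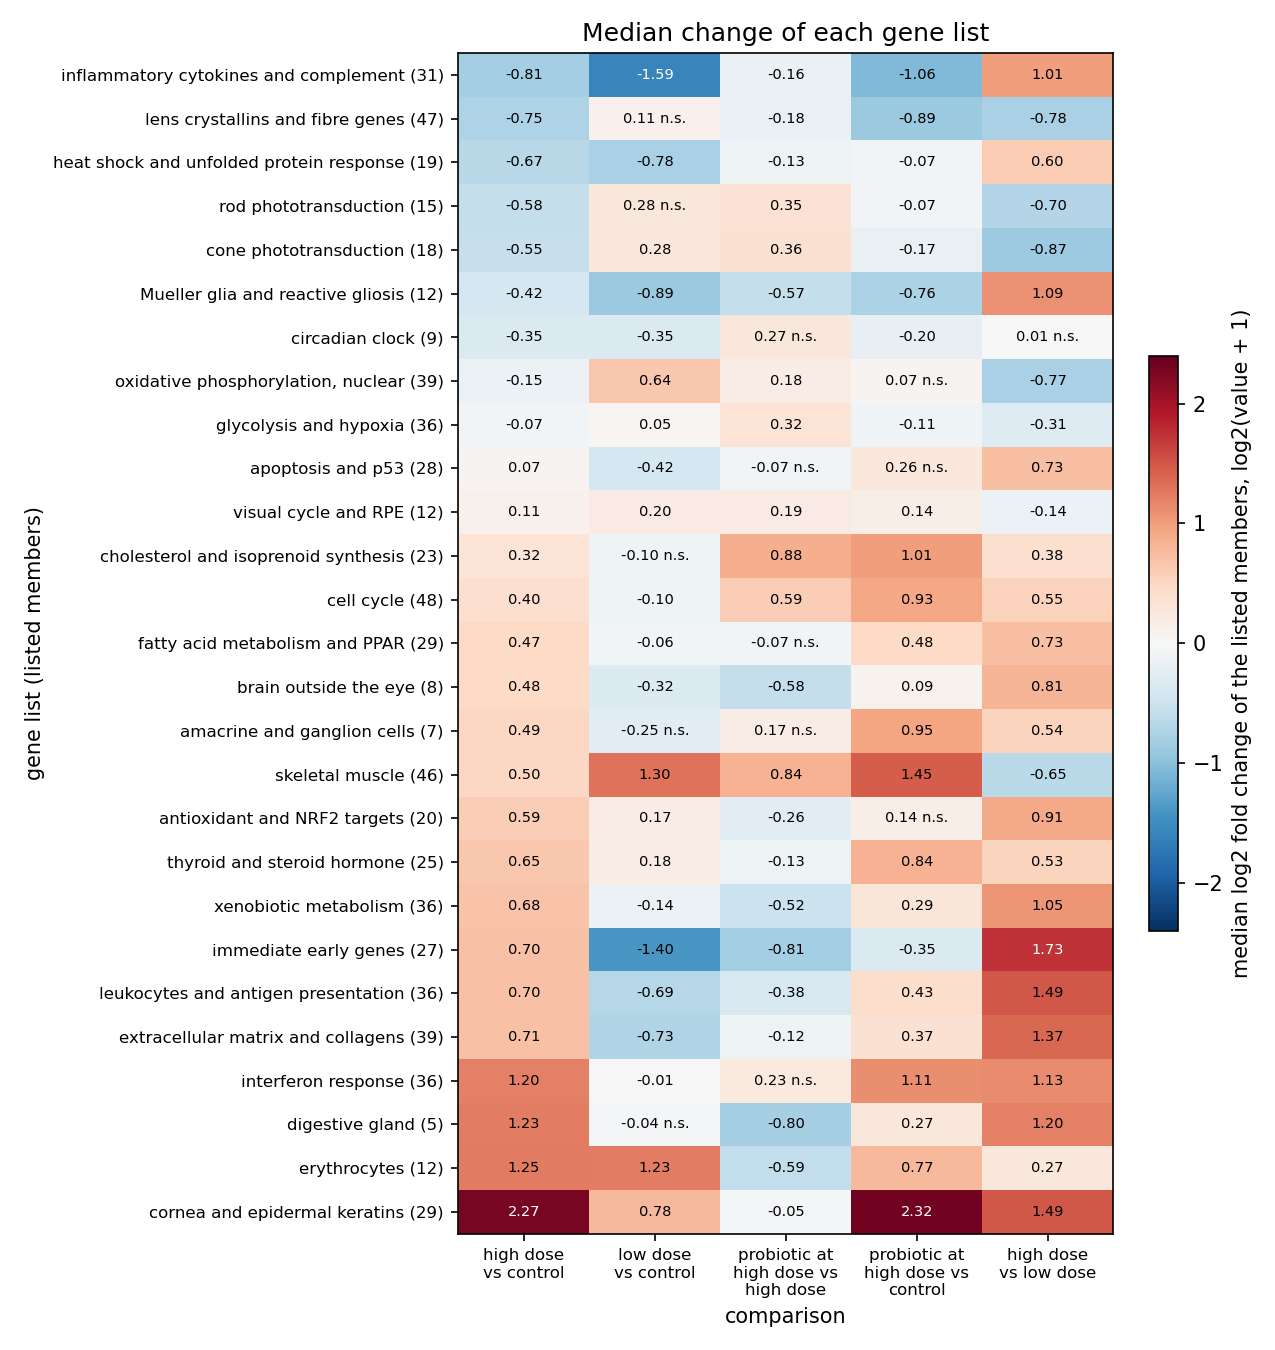
Median log2 fold change of each fixed gene list (rows, with the number of listed members) in each comparison (columns), on the log2(value + 1) scale. Keratins reach 2.27 at the high dose and 2.32 with the probiotic, inflammatory genes -1.59 at the low dose. The mark n.s. shows lists that did not pass fry at an adjusted p of 0.05. Some medians change sign when the values are rescaled, such as those of the visual cycle and p53 lists. Larger ones can too: heat shock genes, high against low dose, go from 0.6 to -0.18 under median-ratio scaling.

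The low dose comparison asks whether a lower concentration changed the eye in the same way. Muscle genes, haemoglobins and genes of oxidative phosphorylation were higher than in control, and inflammatory, immediate early, matrix and leukocyte genes were lower. Of the 46 listed skeletal muscle genes 40 rose and 1 fell, with a median log2 fold change of 1.3. The skeletal actin gene ACTA1 (ENSDARG00000055618) rose from 4.72 ± 0.26 to 55.6 ± 2.29 and the muscle parvalbumin gene pvalb4 (ENSDARG00000024433) from 17.7 ± 1.19 to 145 ± 5.11. The globin genes hbaa1 and HBE1 (ENSDARG00000069734) rose from 134 ± 6.49 to 1673 ± 81.2 and from 9.48 ± 1.66 to 101 ± 4.98. In the erythrocyte list, which holds hbaa1 but not HBE1, 9 of 12 genes rose and 0 fell. A glycolytic enzyme gene, GAPDH (ENSDARG00000043457), rose 11.1-fold to 235 ± 10.2, while the hypoxia-responsive gene NDRG1 (ENSDARG00000010420) fell from 890.4 ± 9.54 to 230.2 ± 2.07; the glycolysis and hypoxia list as a whole had 14 genes higher and 16 lower. Of the 39 nuclear genes of oxidative phosphorylation, 31 rose and 3 fell (median 0.64), among them COX5B (ENSDARG00000068738), from 2.3 ± 0.626 to 12.1 ± 0.463. The keratin gene krt97 (ENSDARG00000000212) went from 222 ± 1.2 to 910.5 ± 41.3, in a list with 19 higher and 8 lower (median 0.78).

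Of the 31 inflammatory genes 28 fell at the low dose and none rose (median log2 fold change -1.59). The cytokine gene il1b stood at 0.127 ± 0.127 against 399 ± 4.42, cxcl8a at 1.1 ± 0.314 against 235 ± 1.49, and the chemokine gene cxcl18b (ENSDARG00000075045) at 5.81 ± 0.614 against 246 ± 3.79. Outside that list, the gelatinase gene MMP9 (ENSDARG00000042816) fell from 505 ± 8.33 to 1.43 ± 0.0884, and lepb, csf3b and scpp8 stood at 0.467 ± 0.0832, 0.399 ± 0.364 and 0.198 ± 0.199. Immediate early genes fell in 23 of 27 cases and rose in 2 (median -1.4). The transcription factor gene FOS (ENSDARG00000031683) went from 242 ± 6.09 to 59.9 ± 1.23 and FOSL1 (ENSDARG00000015355) from 58.8 ± 2.31 to 0.868 ± 0.274. Heat shock genes fell in 14 of 19 cases and rose in 1; hsp70l (ENSDARG00000055723) went from 109 ± 4.07 to 5.94 ± 0.735. Of the matrix genes 30 of 39 fell and 2 rose (median -0.73), with COL10A1 (ENSDARG00000101535) at 2.4 ± 0.546 against 25.3 ± 2.19, and of the leukocyte genes 25 of 36 fell and none rose (median -0.69). The class I antigen presentation gene mhc1uba (ENSDARG00000075963) was listed at 0 in all 3 low dose libraries and at 145, 142 and 148 in control. Of the cone genes 10 rose and 3 fell (median 0.28). Lens genes were mixed, with 17 higher, 13 lower and a median of 0.11 (adjusted p = 0.908 by limma's fry), but passed with a median of 0.52 after median-ratio scaling. Interferon-response genes had 8 higher, 12 lower and a median of -0.01, which turned to 0.11 after that scaling.

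In limma's test 4478 listed genes passed, 1453 higher and 3025 lower, and 1540 changed at least 2-fold. Adjusted p was 5.54e-12 for the muscle list and 3.75e-12 for the inflammatory list by fry. The direction of the whole set rests on the scaling: median-ratio scaling gave 51.4% higher among called genes in place of 32.4%, and moved the median of all listed genes from -0.14 to 0. The complex I gene NDUFS4 (ENSDARG00000052840) was past the test with 51.7 ± 3.79 against 11.8 ± 18.9, but one control library stood at 33.6 and the others at 1.26 and 0.577; its adjusted p was 0.0791 without control replicate 2, 0.0929 without control replicate 3 and 0.051 without low dose replicate 3.

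**Figure D2:**
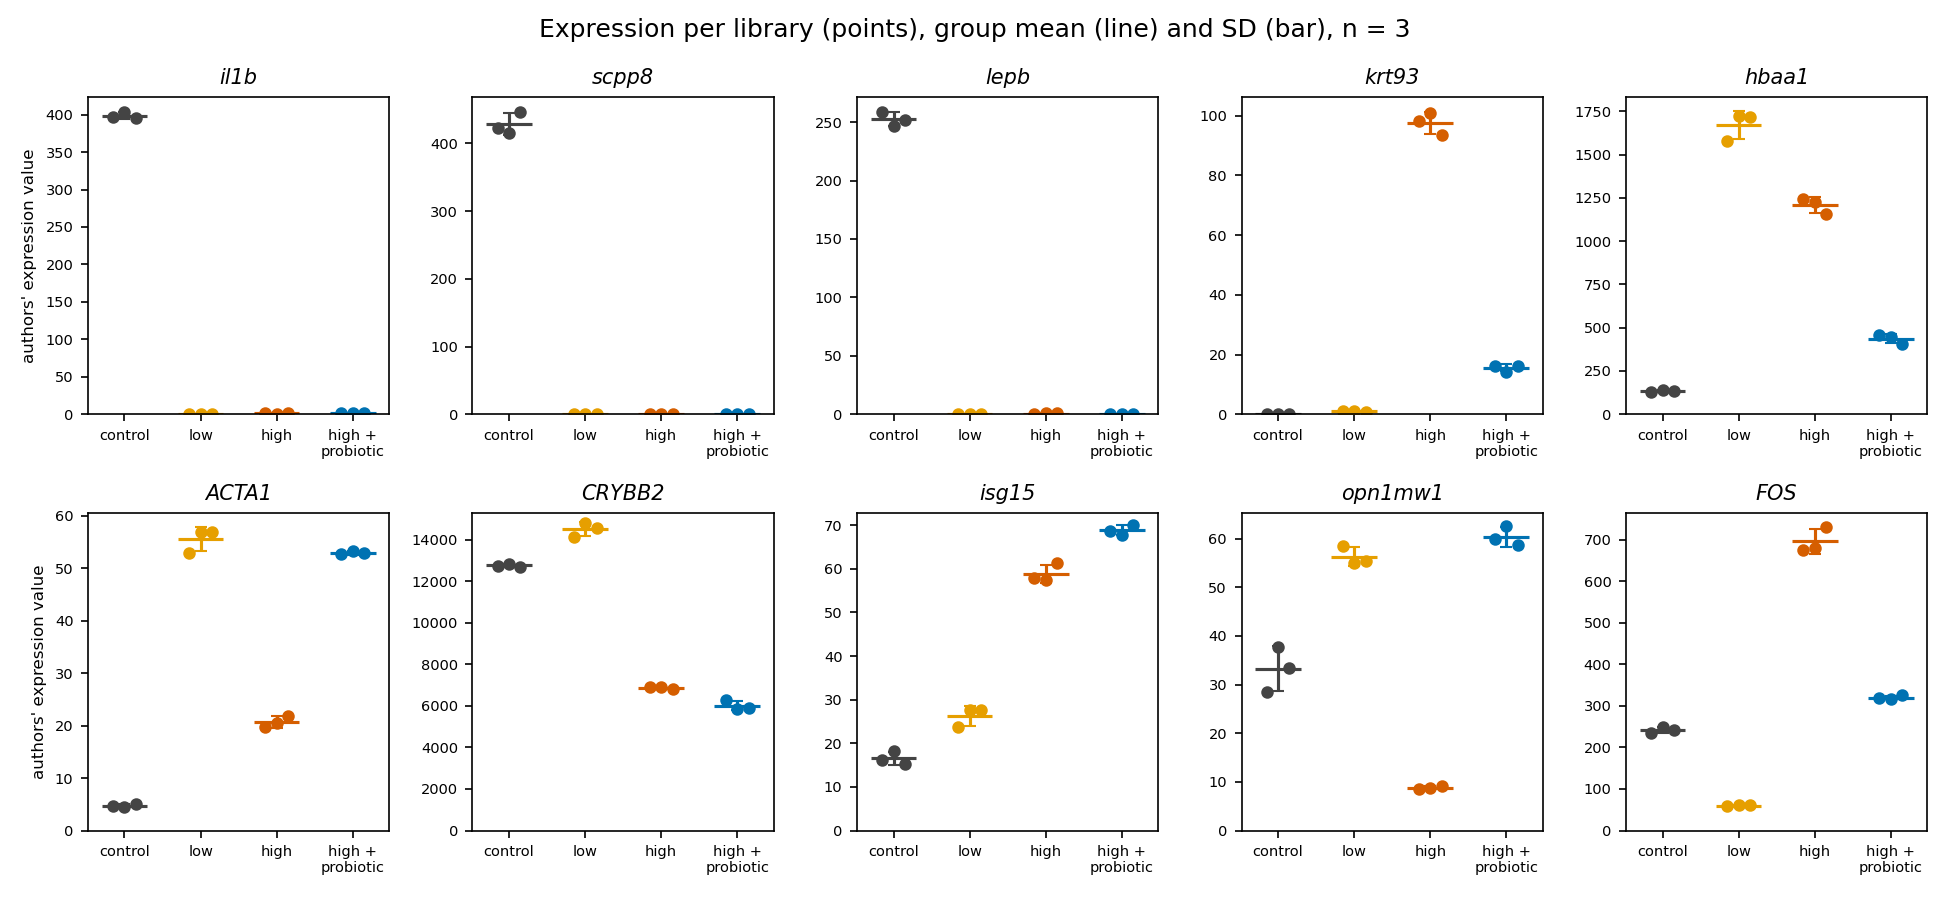
Expression values, as deposited and in an unnamed unit, of 10 genes in each of the 12 libraries by group; points are libraries, lines are means and bars are SD, and each vertical axis is linear and starts at 0. The genes il1b, scpp8 and lepb are high only in the 3 control libraries among the 12, and hbaa1 reaches 1673 at the low dose against 134 in control.

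The high and low dose were also compared with each other. Here 6012 listed genes passed in limma's test, 4703 higher and 1309 lower at the high dose, and 2699 changed at least 2-fold. Median-ratio scaling lowered the share that was higher from 78.2% to 56.4% and the median of all listed genes from 0.56 to 0.14. Matrix genes were higher at the high dose in 37 of 39 cases, leukocyte genes in 33 of 36, interferon genes in 34 of 36 and immediate early genes in 24 of 27, with 1, 0, 0 and 0 lower. Muscle genes were lower in 36 of 46 cases, oxidative phosphorylation genes in 37 of 39 and lens genes in 39 of 47. The gene tgm1l2 stood at 131 ± 1.99 against 0.219 ± 0.119. The genes pvalb5 and mhc1uba were listed at 0 in every low dose library, against 504 ± 19.6 and 302 ± 18 at the high dose. In the other direction, RGS9 (ENSDARG00000045156), which shuts off the photoreceptor light response, stood at 0.493 ± 0.44 against 53 ± 1.88, tnfrsf14 (ENSDARG00000068966) at 0.0874 ± 0.151 against 32 ± 2.05, and NDUFS4 at 0.962 ± 0.984 against 51.7 ± 3.79.

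Both doses were set against the same 3 control libraries. Of the 3264 genes past the test in both comparisons, 2214 changed in the same direction, 859 higher and 1355 lower in both. Independent lists with these totals would give 3282 genes in both, so the overlap itself was no larger than that. They would give 1452 genes in the same direction, 707 of them higher and 746 lower. A further 889 genes were higher at the high dose and lower at the low dose, where independent lists give 1471. Across listed genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with r = 0.54. Unchanged groups simulated against the same controls gave a median r of 0.49 and a highest r of 0.54. Sharing controls gives unchanged groups such an r however small the noise is, so r cannot decide whether the changes are shared. The simulated groups gave a median covariance of 0.01 and a highest of 0.02, and the observed covariance was 0.53. Control noise of the fitted size was thus too small to give the observed covariance. The simulation holds no offset of the control group as a whole, which would move both comparisons alike. The covariance therefore does not show a shared effect of the monomer. The 3 controls could not be split between the comparisons, and independent lists make no allowance for shared controls.

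**Figure D3:**
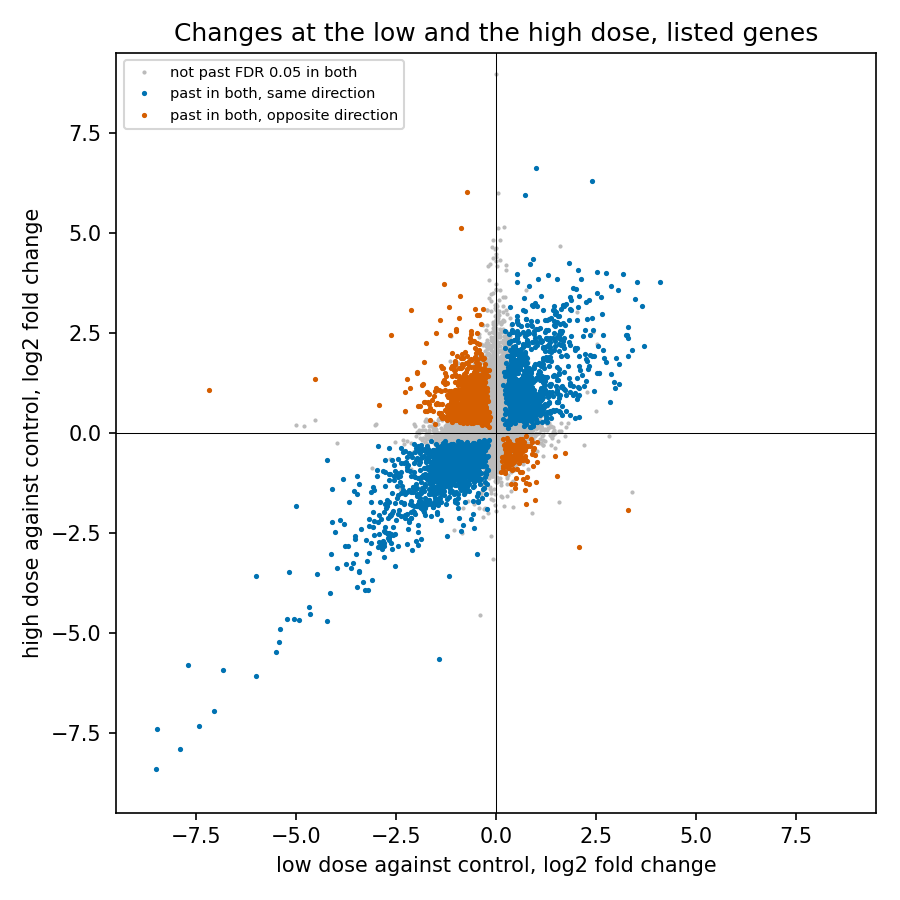
Log2 fold changes of the listed genes at the low dose (horizontal axis) and the high dose (vertical axis) against the shared control, on the log2(value + 1) scale; each point is a gene. Blue points (2214) passed the test in both with the same sign and orange points (1050) with opposite signs.

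The probiotic comparison sets fish given the high dose and the bacterial feed against fish given the high dose alone. If the feed came after the exposure, the groups also differ in time without the monomer. Muscle, cell cycle, cholesterol synthesis and photoreceptor genes were higher with the probiotic, and immediate early, haemoglobin, xenobiotic metabolism and leukocyte genes were lower. Of the 46 muscle genes 40 rose and none fell (median log2 fold change 0.84); the muscle calcium pump gene atp2a1 (ENSDARG00000020574) went from 20.2 ± 0.132 to 65.3 ± 2.17 and ACTA1 from 20.7 ± 1.1 to 53 ± 0.355. Of the 48 cell cycle genes 36 rose and 1 fell (median 0.59), among them CCNE2 (ENSDARG00000098529), from 4.69 ± 0.275 to 9.51 ± 0.68, and RRM2 (ENSDARG00000078069), from 4.45 ± 0.386 to 10.4 ± 1.61. Cholesterol and isoprenoid genes rose in 17 of 23 cases and fell in 2 (median 0.88); FDPS (ENSDARG00000040890), an enzyme of isoprenoid synthesis, went from 12.1 ± 0.564 to 26.9 ± 1.54 and the lipoprotein receptor gene ldlra (ENSDARG00000029476) from 3.81 ± 0.405 to 11.3 ± 0.391. Of the 18 cone genes 10 rose and 5 fell (median 0.36), and the green cone opsin gene opn1mw1 (ENSDARG00000097008) rose from 8.84 ± 0.311 to 60.4 ± 2.02, above the control value of 33.2 ± 4.65. The cone arrestin gene ARR3 (ENSDARG00000056511) rose from 921 ± 23.9 to 1539 ± 63.3. Of the 15 rod genes 10 rose and 2 fell (median 0.35), with the transducin gene GNAT1 (ENSDARG00000044199) at 2532 ± 54.8 against 1883 ± 6.32 and the phosphodiesterase subunit gene PDE6G (ENSDARG00000101984) at 1029.8 ± 29.1 against 1523 ± 33.7.

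Immediate early genes fell in 20 of 27 cases and rose in 1 with the probiotic (median log2 fold change -0.81). FOS went from 695 ± 30.9 to 320.1 ± 4.11 and the growth arrest gene BTG2 (ENSDARG00000020298) from 293 ± 12.8 to 97.4 ± 4.74. Xenobiotic metabolism genes fell in 22 of 36 cases and rose in 5 (median -0.52), with the cytochrome P450 genes cyp2ad2 (ENSDARG00000021172) and cyp2k17 (ENSDARG00000104529) at 0.213 ± 0.0938 against 8.85 ± 0.681 and at 0.373 ± 0.144 against 8.73 ± 1.39. Of the 12 erythrocyte genes 8 fell and 1 rose, hbaa1 to 438 ± 26 and CREG1 (ENSDARG00000105154) from 63.2 ± 2.32 to 30 ± 0.699, and leukocyte genes fell in 19 of 36 cases and rose in 5. All 5 digestive gland genes fell. The lipoxygenase gene alox5b.2 (ENSDARG00000043089) rose from 1 ± 0.386 to 111 ± 6.11, RGS9 from 0.493 ± 0.44 to 17.2 ± 1.08 and tnfrsf14 from 0.0874 ± 0.151 to 10.6 ± 0.472. The class II genes mhc2dga (ENSDARG00000103716) and mhc2dgb (ENSDARG00000104635) were listed at 0 in every high dose library and at 9.23, 10.1 and 10.4 and at 8.95, 9.3 and 8.9 with the probiotic. The epithelial adhesion gene epcam (ENSDARG00000040534) rose to 23.1, 31.3 and 17.9 from 0.358, 0 and 0, but it also differed within the control group, at 76.3, 62.7 and 0. Of the genes that fell most, pvalb5 dropped from 504 ± 19.6 to 0.158 ± 0.145, tgm1l3 to 1.95 ± 0.357, prss60.1 (ENSDARG00000070713) from 23.7 ± 1.34 to 0.023 ± 0.0208, capsla (ENSDARG00000103521) from 40.9 ± 3.55 to 1.34 ± 0.516 and SMKR1 (ENSDARG00000107526) from 23.8 ± 4.35 to 0.406 ± 0.238, and malb was listed at 0 in all 3 probiotic libraries.

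In limma's test 4654 listed genes passed, 1893 higher and 2761 lower (40.7% higher, and 47.2% after median-ratio scaling), and 1216 changed at least 2-fold. Adjusted p by fry was 4.27e-10 for muscle, 3.09e-08 for cell cycle, 8.67e-07 for cholesterol synthesis, 5.31e-08 for cone genes and 5.31e-08 for immediate early genes. The keratin list had 9 genes higher, 9 lower and a median of -0.05, and passed limma's fry as lower (adjusted p = 0.00767). It no longer passed after median-ratio scaling (median 0.06, adjusted p = 0.418 by limma's fry) or upper-quartile scaling (median 0.1, adjusted p = 0.172 by limma's fry).

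With the probiotic, high dose fish were also set against the control. Here 5687 listed genes passed in limma's test, 3459 higher and 2228 lower, and 2093 changed at least 2-fold. Median-ratio scaling lowered the share that was higher from 60.8% to 50.8% and the median of all listed genes from 0.18 to 0.03. Keratin genes were higher in 25 of 29 cases with 1 lower (median log2 fold change 2.32), muscle genes in 44 of 46 with 1 lower (1.45), cell cycle genes in 45 of 48 with 1 lower (0.93), cholesterol genes in 19 of 23 with 2 lower (1.01) and interferon genes in 29 of 36 with 1 lower (1.11). Lens genes were lower in 43 of 47 cases with 1 higher (-0.89), and inflammatory genes in 22 of 31 with 4 higher (-1.06). The gene il1b stood at 1.6 ± 0.158, lepb at 0.397 ± 0.147 and scpp8 at 0.704 ± 0.106, close to the other exposed groups and far below control. The gene vtg1 stood at 18.3 ± 0.651 against 0.0315 ± 0.0451, and alox5b.2 at 111 ± 6.11 against 0.387 ± 0.22. The proteoglycan gene SPOCK3 (ENSDARG00000070266) stood at 67, 72.8 and 78.1 against 0.095, 0.125 and 4.48, and it differed within the low dose group, at 75.3, 0.507 and 0.609.

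Of the 5830 genes past the test at the high dose, 2469 changed in the opposite direction with the probiotic and passed that test too, while 944 moved further from control. Over all listed genes, 58.5% passed between the probiotic and the high dose group. Of the 5830 genes, 64.7% moved toward the control, past the test or not, against a median of 53.1% and a highest of 54.4% in simulated probiotic groups with the high dose means. Measured against control, 4036 of the 5830 genes still passed in the same direction with the probiotic, and 297 in the other. Medians over the simulations were 6020.5 genes past the test at the high dose and 5670.5 still past it in the same direction. The simulation allows only for noise around the high dose means and does not repeat the choice of genes for differing between groups. A group that differs from the high dose for any reason could depart from it, so it cannot show a reversal of the monomer's effect. The 1797 genes at least 2-fold higher at the high dose had a median log2 fold change of 1.49, which was 0.95 with the probiotic and 0.03 at the low dose, and 1053 of them were called in the opposite direction with the probiotic. The 588 genes at least 2-fold lower had a median of -1.4 at the high dose, -1.19 with the probiotic and -1.37 at the low dose, and 221 of them were called in the opposite direction with the probiotic. Both sets were picked on the high dose libraries, which can by itself bring the probiotic group nearer to control. Their sizes were not simulated.

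Markers of tissues that lie in and around the eye differed between the groups. The mean log2 value of the keratin list was 4.5 ± 0.121 in control, 4.88 ± 0.044 at the low dose, 6.48 ± 0.063 at the high dose and 6.5 ± 0.032 with the probiotic. For muscle it was 1.35 ± 0.047, 2.71 ± 0.025, 2.02 ± 0.012 and 2.9 ± 0.014 in the same order, for erythrocytes 1.84 ± 0.003, 3.3 ± 0.077, 3.5 ± 0.066 and 2.91 ± 0.058, and for lens 8.41 ± 0.025, 8.4 ± 0.027, 7.72 ± 0.015 and 7.59 ± 0.012. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest it can give, for each of these lists between high dose and control, and an adjusted p of 0.12 over the comparisons in this family. In the same exact test and comparison p was 0.4 for the rod list and 0.6 for the visual cycle list. The rod list varied in control (6.66 ± 0.242), where the recoverin gene RCVRN (ENSDARG00000019902) stood at 1.24 in one control library and at 171 and 180 in the others.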

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

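The scaling, control state, tissue share and muscle tests below were chosen only after the result was seen; the neutrophil, pool and split tests were not. For 13 gene lists limma's fry passed in opposite directions at the 2 doses against control and for the difference between the doses. In 11 of them the medians also had opposite signs; in the visual cycle (0.11 at the high and 0.2 at the low dose) and antioxidant lists (0.59 and 0.17) they did not. Among the 11, the median log2 fold changes of high against low dose were -0.87 for cone genes, 1.37 for matrix, 1.49 for leukocyte and -0.77 for oxidative phosphorylation genes. The median of all listed genes between the doses was 0.56, so the cell cycle value below is no larger than that. For immediate early genes (1.73) the rise at the high dose no longer passed after median-ratio scaling, where its median was 0.26. For interferon (1.13), xenobiotic (1.05), fatty acid (0.73) and cell cycle genes (0.55) the low dose direction turned under rescaling, and for apoptosis genes (0.73) the high dose direction did. The fatty acid difference between the doses did not hold either. Its median was -0.01 after median-ratio scaling and 0.04 after upper-quartile scaling, where it no longer passed (adjusted p = 0.0789 by limma's fry). For brain genes (0.81) the low dose change no longer passed after rescaling. Groups of 3 were not tested for single libraries out of place.

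Inflammatory genes such as il1b and cxcl8a, and MMP9 and lepb outside their list, were far higher in the 3 control libraries than in the 9 exposed ones. The authors' scaling is argued against, since the inflammatory list's median at the low dose was still -1.33 after median-ratio scaling. More neutrophils in the control eyes could not be decided: the highest median over the 11 listed of 23 fixed markers was -0.51, at the high dose, between the bounds set in advance, and was -1.08 when s100a10b, a doubtful marker left out only afterwards, was not counted. A state of the control fish at sampling could not be decided either, and the design ties that state to the control group. The list did not fall with dose, with a median of 1.01 for high against low dose. Such a state alone would leave the exposed groups together, but 21 of 31 listed genes were higher at the high than the low dose and 1 lower. All listed genes had a median of 0.56 in that comparison, and of 0.14 after median-ratio scaling. How far the list differs between the doses thus rests partly on the scaling. An effect of the monomer that is complete at the low dose would leave both doses alike. In the authors' scaling the list as a whole does not show this. Its medians against control were -1.59 at the low and -0.81 at the high dose. No rescaled high dose median was set beside the -1.33 at the low dose, so the list cannot decide it. For single genes an effect complete at the low dose also stays open, such as for lepb, at 0.467 ± 0.0832 at the low and 0.583 ± 0.17 at the high dose.

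Epidermal, muscle, blood and lens genes stood at different levels in the 4 groups, and growth or repair of these tissues in the fish was not tested. A single lower share of eye tissue at the high dose would raise other tissues alike, but the highest and lowest medians of the epidermal, muscle, blood and matrix lists differed by 1.77. Scaling does not account for the epidermal rise, whose median was 1.85 after median-ratio scaling. More muscle carried along at dissection may explain part of the muscle difference between probiotic and high dose, since the log2 ratios of 14 muscle genes with a mean of at least 10 had an SD of 0.4 around a median of 1.28. The ratios ran from 0.38 to 1.94, which goes against one shared ratio, and both this form of the test and its minimum mean, lowered from a higher one that left too few genes, were chosen after looking.

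Libraries of a group differed by a few percent in their most abundant genes, and by more in the others. If the 3 libraries of a group come from one pool of eyes, tissue lists should vary no more between them than random lists, and 1 of 12 list and group pairs varied beyond the 95th percentile. That pair was the keratin list in control, which holds epcam, at 76.3, 62.7 and 0 in the control libraries. The listed genes were chosen for differing between groups, which favours genes that vary little within them, so a single pool cannot be told apart from separate fish.

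For each count of genes, the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 split, the real one, reached the real count. In fits of 2 groups alone the real split called 5774 genes for high dose against control, 4211 for low dose against control, 4684 for probiotic against high dose, 5606 for probiotic against control and 5975 for high against low dose, and the highest other split called 0 in each. The listed genes were chosen for differing between these groups, and a mixed split puts that difference into the spread. Few calls in the other splits were thus largely fixed in advance, and the splits cannot decide whether chance made the groups.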

How the results depend on the processing

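Rescaled list medians, the list tests with a replicate block and the rescaled probiotic overlap were chosen only after the result was seen. Requiring a log2 fold change of at least 1 left 2385, 1540, 1216, 2093 and 2699 genes for high dose against control, low dose against control, probiotic against high dose, probiotic against control and high against low dose, by construction of that limit. The other settings moved no total by over 1.5 times, but under median-ratio and upper-quartile scaling the genes higher at the low dose went from 1453 to 2423 and 2343, and those lower at the high than the low dose from 1309 to 2476 and 2306. Leaving out 1 replicate gave 5538 to 5589, 4169 to 4217, 4057 to 4358, 5324 to 5453 and 5785 to 5824 genes in the same order. It gave 27, 22 to 23, 22 to 23, 22 to 24 and 26 to 27 lists, r of 0.54 to 0.55, and 2207 to 2293 genes opposite with the probiotic (2237 and 2280 under the 2 scalings). Replicate numbers did not pair the libraries (correlations -0.08 to 0.11), and a replicate block gave 5824, 4484, 4601, 5667 and 6012 genes. Of 768 alternatives for named genes 765 kept direction and call, and the other 3 were for NDUFS4 at the low dose (2.83, 2.57 and 3.36). The named genes were picked for large changes or small adjusted p in these same libraries, which favours keeping their call.

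Of the rescaled list medians 33 reversed and 206 kept direction and call, and the cause was not tested. Under median-ratio and upper-quartile scaling these were, at the high dose, visual cycle (-0.33, -0.23) and apoptosis (-0.23, -0.16). At the low dose they were interferon (0.11, 0.1), xenobiotic (0.02, 0.02), fatty acid (0.19, 0.17), cell cycle (0.07, 0.05) and cholesterol (0.25, 0.22). For probiotic against high dose they were keratins (0.06, 0.1) and fatty acid (0.04, 0.08). For probiotic against control they were visual cycle (-0.11, -0.01), oxidative phosphorylation (-0.25, -0.11), and under median-ratio scaling brain (-0.05) and antioxidant (0). For high against low dose they were erythrocytes (-0.36, -0.27), heat shock (-0.18, -0.07), cholesterol (-0.2, -0.14), circadian (-0.28, -0.16), and under median-ratio scaling fatty acid (-0.01). A further 20 lost their call and 11 gained one. Planned count-based and background-based alternatives (a Wald test, count normalisation and camera) were not run, since the values are not counts and the genes are a chosen set.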

Other observations

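The counts of genes near 0 below were chosen only after the result was seen, and no tests of an explanation are given in this part. The antigen presentation and yolk genes given here were picked after their values were seen. The class I gene mhc1zba stood at 85.1 ± 5.3 in control, 4.58 ± 1.26 at the low dose, 70.7 ± 1.38 at the high dose and 43.4 ± 4.18 with the probiotic. The class II gene mhc2dbb stood at 5.97, 5.92 and 7.55 at the high dose and at 0.058 or below in control. The yolk gene vtg7 was listed at 0 in control and at 4.2, 3.2 and 3.97 at the high dose.

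Of the listed genes, 119 had a library at 10 or more and another at 0.1 or less, and in 16 of them both lay inside one group, so a value near 0 is not shown to be absence of expression. Counts of list members past the test, adjusted over the list alone, equalled those over all genes in 107 of 135 list and comparison pairs, and differed by more than 2 in 1, cell cycle at the low dose, with 11 over all genes and 3 adjusted over the list alone.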
